A study of Rattus norvegicus with 24 samples.

How the data were processed

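Hypothalamic RNA of 24 Sprague Dawley rats, 1 array per rat, was measured on Illumina bead arrays, on which each probe reports the brightness of labelled RNA bound to it. Per the labels, RNA was column-purified, its integrity was examined by capillary electrophoresis, and it was amplified into biotin-labelled cRNA with a kit made for these arrays. The deposited intensity of each probe was not normalized, per the file headers, and the lowest values of each array lay well above 0, so background had not been subtracted. Beside each intensity the deposited table gives a detection p-value, which moves in 825 equal steps and ranks the probe's signal against background. A further deposited table holds the authors' processed intensity of the same arrays. Its values kept the rank order of the raw intensity on every array (Spearman correlation of 1), shared 1 maximum of 62830 and near-equal medians, and were on a linear scale, so these values are quantile normalized and not centred. The scanner software and the authors' normalization tool are not given in the sources used here.

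The table holds 22523 probes for 21886 target identifiers. The files do not pair these identifiers with genes, and 0 of 22523 probe identifiers were found in the reference table of rat gene names (assembly GRCr8), so no gene is named and transcripts are given by probe identifier. The 31 gene lists fixed before the data were examined, and the list tests planned with them, are not analysed here for that reason. The rule for choosing named genes, also fixed before the data were examined, ranks genes with a symbol by the size of their log2 difference. Without symbols it was applied to probe identifiers and limited, for each comparison, to the 2 largest rises and 2 largest falls among transcripts past the threshold, taken first from the fit of all 24 arrays and then from the fit of 22 arrays described next.

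Intensities were background-corrected and normalized with neqc in limma 3.58.1 under R 4.3.3. This fits a normal plus exponential model with the background inferred from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. The offset shrinks differences between dim probes. Background correction as a whole nevertheless enlarged the differences of the named probes. Without it all 17 were smaller, at 35.5% to 98.4% of the log2 size. Probes with a detection p-value under 0.05 on at least 4 arrays were kept, and the brightest probe on average stood for each target identifier, in place of the planned choice by gene symbol. This left 12262 transcripts. A linear model with 1 mean per stage was fitted to all 24 arrays with lmFit and eBayes, with a moderated F test over the 5 stages and 5 two-sided comparisons, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The number of arrays, 4 or 5 per stage, limits the precision. Slide and scan date are not given in the sources used here, so neither could enter a fit.

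On 2 arrays, juvenile replicate 4 and early proestrus replicate 2, the share of probes detected was under 0.5 times that of the median array. They stayed in the planned fit. A fit without them, on 22 arrays with normalization and filter repeated and 12186 transcripts left, was added after seeing the data. It stands beside each planned count, and values by stage come from it. A probe detected on no array of a stage is given as a bound after background correction, the bright stage's mean against the higher, on each array of the dim stage, of the probe's own value and the lowest value among detected probes. Where only some arrays of a stage detected a probe, their number is given, and its log2 difference rests partly on values near background. Where at least 1 but under 50% of the arrays of a stage did so, no size of the difference is given.

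The fits were tested on simulated data with the transcripts' own means and spreads, 20 draws per comparison and 200 changed transcripts per draw. Noise was drawn independently for each transcript and array. The simulation therefore holds no shift shared across an array, and the share of false calls in the real fits may differ. On 22 arrays the fit recovered 86.6% of 2-fold changes in early proestrus against late juvenile and 93.1% in late proestrus against early juvenile, the lowest and the highest of the 5 comparisons. The mean share of false calls lay between 5.11% and 5.77% per comparison, and the highest in a single draw was 11%. With the 2 arrays of low detection put back at their measured values, recovery of 2-fold changes fell to between 5.15% in juvenile against early juvenile and 13.7% in late proestrus against early proestrus.

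The alternatives tried were log2 intensity without background correction, median scaling in place of quantile normalization, the authors' processed values, no filter on dim probes, a filter asking for a detection p-value under 0.01 on every array, all probes of a target, only the arrays of the 2 stages compared, array weights, a robust fit with an intensity trend, an added fold of at least 1.5, and leaving out each array in turn. Added after seeing the data were the 22 arrays, the same alternatives on them, a fit without their 2 dimmest arrays, array brightness as a covariate, 2 further comparisons with the late juvenile stage and a fit without that stage.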

Results

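The hypothalamus, the brain region that drives the pituitary and ovaries, was profiled across the approach to puberty in rats. The series' title names the hypothalamic control of puberty as its subject. Early juvenile rats of 21 days (n = 5), juvenile rats of 26 days (n = 5), late juvenile rats of 29 days (n = 5), rats in early proestrus, before ovulation (n = 4), and rats in late proestrus, on the day of first ovulation at 31 days (n = 5), gave 1 array each. The early proestrus rats are labelled as 29, 30, 31 and 32 days old, although the design text gives a range of 29 to 31 days for them. Animal numbers in the labels are unique, so each array was taken as a separate rat. They run from 164 to 168 in the early juvenile stage, from 28 to 37 in the late juvenile stage and from 1 to 20 in the other stages. In comparisons with the early or late juvenile stage, stage therefore cannot be told apart from animals or processing peculiar to that group.

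Of the 24 arrays, 22 detected between 45.5% and 51.7% of 22523 probes at a detection p-value under 0.05, with mean raw signals from 513.7 to 1025. Juvenile replicate 4 detected 19.5%, with a mean signal of 194.3. Early proestrus replicate 2 detected 6.33%, where background alone would give about 5%, and its brightest probe reached 479.57 against 54874 or more on each of the 22 other arrays. Both entered the planned fit of 24 arrays. The median standard error of a log2 difference was 0.429 in that fit for juvenile against early juvenile and 0.143 without the 2 arrays, so each planned count is followed by the count on 22 arrays. Among those 22, mean raw signal was 705.1 ± 70.2 (SD, n = 5) in the late juvenile stage and between 835.2 and 906.8 in the other stages.

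**Figure D1:**
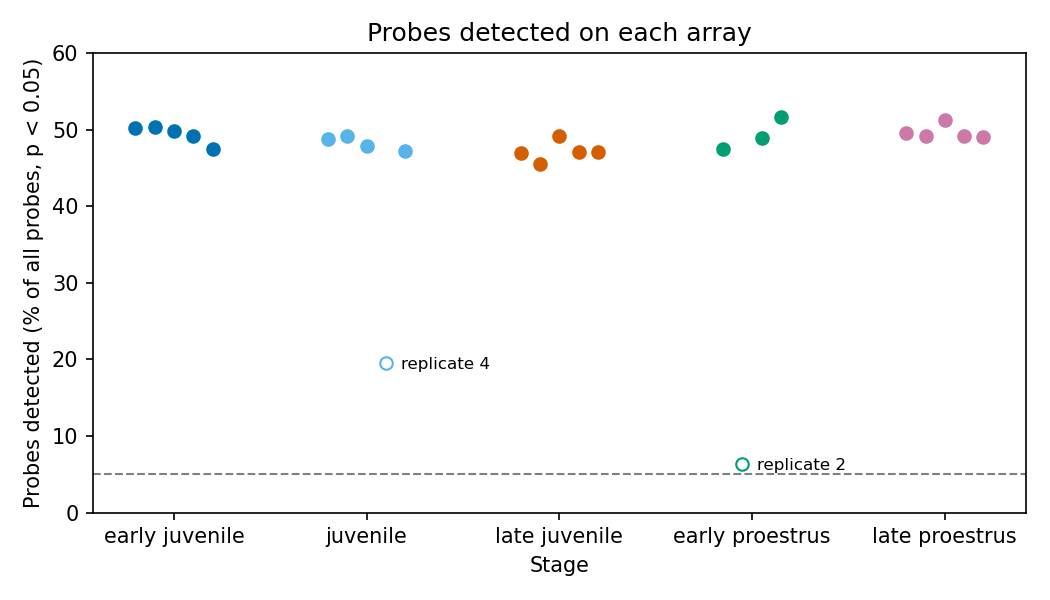
Share of probes detected on each array, in percent of all probes, by stage. Filled points are the 22 arrays between 45.5% and 51.7%, open points are juvenile replicate 4 (19.5%) and early proestrus replicate 2 (6.33%), and the dashed line marks the 5% that background alone would give.

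Late juvenile arrays stood farthest from the rest, though stage cannot be told apart from animals or processing peculiar to that group. Any difference among the 5 stages passed the moderated F test for 19 transcripts on 24 arrays and for 2676 of 12186 on 22 arrays. A fit of all 24 arrays with array weights, which came to 0.0118 and 0.00244 for those 2 arrays, called 4309. For 1625 of the 2676 transcripts (60.7%) the late juvenile mean lay farthest from the mean of the other 4 stages, 790 above it and 835 below. The early juvenile mean lay farthest for 798 (29.8%), the late proestrus mean for 128, the early proestrus mean for 65 and the juvenile mean for 60. Among transcripts not past the test, the late juvenile mean was farthest for 36.2% and the early juvenile mean for 23.9%. On the first principal component of the 22 arrays, with 23.9% of the variance, late juvenile arrays scored from 21.6 to 29.6 and early proestrus replicate 1 scored 7.63, while the other 16 scored between -15 and 1.94. The second component, with 15.1%, held juvenile replicate 5 at -30.1 and late juvenile replicate 1 at -30.2, the 2 dimmest of the 22 arrays. The count rose to 4163 without those 2 arrays.

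**Figure D2:**
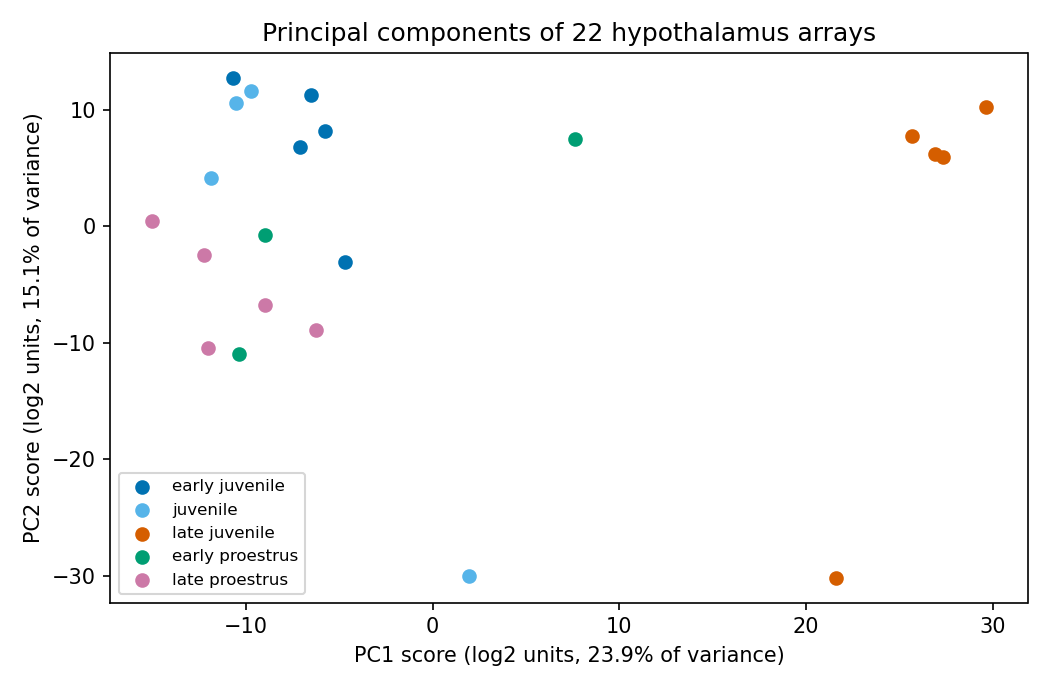
Scores of the 22 arrays on the first and second principal components of normalized log2 intensity, coloured by stage. The 5 late juvenile arrays score from 21.6 to 29.6 on the first component, and the 2 dimmest arrays lie near -30 on the second.

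**Figure D3:**
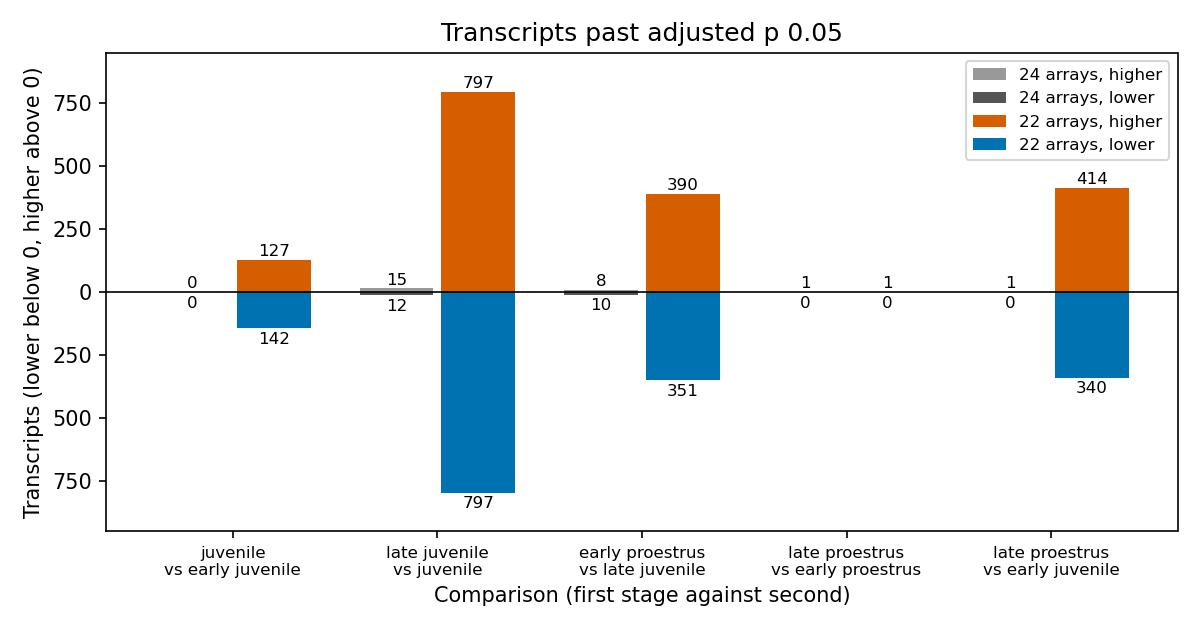
Transcripts past an adjusted p of 0.05 in each comparison, higher above 0 and lower below 0, for the planned 24 arrays (grey) and the 22 arrays without juvenile replicate 4 and early proestrus replicate 2 (coloured). Late juvenile against juvenile has the most, 797 higher and 797 lower on 22 arrays, and late proestrus against early proestrus has 1.

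From day 21 to day 26, the early to mid juvenile step, probe ILMN_1352660 showed the largest fall among transcripts past the threshold on 22 arrays, from 8.95 ± 0.38 (SD, n = 5) to 7.10 ± 0.17 (SD, n = 4) on the log2 scale (difference -1.85, SE 0.23, limma adjusted p = 0.000455). Its means stayed between 6.69 and 7.20 in the later stages, where single arrays ran from 5.78 to 7.48. ILMN_1358038 fell by 2.07 and did not pass (limma adjusted p = 0.0703). ILMN_1351340 fell by 1.76, from 7.65 ± 0.82 (SD, n = 5), with 2 of 4 juvenile arrays detecting it (limma adjusted p = 0.0330), and lost the call without any 1 of 8 arrays, with an adjusted p of up to 0.0905. ILMN_1355623 rose by 1.22, from 6.33 ± 0.12 (SD, n = 5) to 7.55 ± 0.26 (SD, n = 4), and ILMN_1366573 rose by 1.06, from 5.95, with 4 of 5 early juvenile arrays detecting it, to 7.01. The sizes of the 4 called differences depend on background correction: without it they were -1.10, -0.73, 0.51 and 0.38, and with the authors' processed values -1.08, -0.71, 0.49 and 0.36. On 22 arrays 269 transcripts passed, 127 higher and 142 lower in juvenile rats. On 24 arrays limma called 0 of 12262, with 352 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0532. Array weights called 942. The 22-array count fell to 91 without early juvenile replicate 1 and to 99 without juvenile replicate 1.

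From day 26 to day 29, probe ILMN_1358715 rose from near background, 5.55 ± 0.40 (SD, n = 4) with 1 of 4 juvenile arrays detecting it, to 9.16 ± 0.67 (SD, n = 5), where all 5 did (limma adjusted p = 7.4e-08). ILMN_1349776 was at 7.81 ± 0.46 (SD, n = 5) in late juvenile rats, against 7.32 on juvenile replicate 1 and 4.97 to 5.27 on the other 3 juvenile arrays, again with 1 of 4 detecting it. ILMN_1361093 fell by 2.65, from 9.62 ± 0.14 (SD, n = 4) to 6.97 ± 0.58 (SD, n = 5). ILMN_1650254, at 11.32 ± 0.09 (SD, n = 4) in juvenile rats, was lower on each late juvenile array, at 6.04, 5.82, 5.43, 5.02 and 10.2. Of these 5 arrays 2 detected it, so its fall has no exact size, as the 2 rises before it have none, while all 17 arrays of the other stages lay between 11.2 and 11.6. Without background correction the difference of ILMN_1361093 on 22 arrays was -1.65, and with the authors' processed values -1.62. The planned fit called 27 transcripts, 15 higher and 12 lower in late juvenile rats. Leaving out 1 array gave 11 to 431 there, with 13 higher and 32 lower without juvenile replicate 4. Without early proestrus replicate 2 it gave 285 higher and 146 lower. The call was lost without any 1 of 20 arrays for ILMN_1349776, 19 for ILMN_1650254 and 4 for ILMN_1361093 in that fit. All 27 were called with the same sign among the 1594 of the 22-array fit, 797 higher and 797 lower. Leaving out 1 array changed that count to between 1039 and 2410. With all probes kept on 22 arrays, 51 of 240 targets with more than 1 probe had a called probe in this comparison. The 2 probes compared had the same sign for 38 of the 51, and both were called for 5. With median scaling in place of quantile normalization, which moves the median of all transcripts to -0.161, the 22 arrays gave 330 higher and 2285 lower, so the balance of directions holds only relative to each array's own distribution.

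From the late juvenile stage to early proestrus, at overlapping ages, ILMN_1358715 fell to near background, 5.66 ± 0.50 (SD, n = 3) with 1 of 3 early proestrus arrays detecting it. ILMN_1361093 rose by 2.50 to 9.46 ± 0.27 (SD, n = 3), where its juvenile mean was 9.62. ILMN_1376698 rose to 8.44 ± 0.21 (SD, n = 3) from 7.72 on late juvenile replicate 2 and 5.50 to 5.83 on the other 4 late juvenile arrays, 2 of 5 detecting it, so its rise has no exact size, and its mean in the 3 remaining stages lay between 8.45 and 8.54. ILMN_1374870 fell by 1.97, from 10.16 ± 0.06 (SD, n = 5) to 8.19 ± 0.36 (SD, n = 3). Without background correction the differences of ILMN_1361093 and ILMN_1374870 on 22 arrays were 1.53 and -1.48, and with the authors' processed values 1.49 and -1.46. The planned fit called 18 transcripts, 8 higher and 10 lower in early proestrus, all of them called with the same sign among the 741 of the 22-array fit (390 higher, 351 lower). In the planned fit the call was lost without any 1 of 6 arrays for ILMN_1376698, 16 for ILMN_1361093 and 20 for ILMN_1374870. The 22-array count was 280 without early proestrus replicate 3 and 292 without replicate 4, each leaving 2 arrays in that stage. Median scaling moved the median of all transcripts to 0.197 and gave 1640 higher and 137 lower.

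From early to late proestrus 1 transcript passed on 24 and on 22 arrays, ILMN_1355623. It rose from 7.84 ± 0.69 (SD, n = 3) to 9.80 ± 0.31 (SD, n = 5), and all 5 late proestrus arrays lay above the 3 of early proestrus (log2 difference 1.97, SE 0.24, limma adjusted p = 0.000751 on 22 arrays and 0.0305 on 24). The difference on 22 arrays was 1.38 without background correction and 1.35 with the authors' processed values. On 22 arrays 497 transcripts (4.08%) had an unadjusted p under 0.05. On 24 arrays the call was lost when any of 15 single arrays was left out. On 22 arrays the count stayed at 1 without each array in turn and fell to 0 when the fit held the arrays of these 2 stages alone.

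Over the whole span, from early juvenile to late proestrus, ILMN_1355623 rose from 6.33 ± 0.12 (SD, n = 5) to 9.80 ± 0.31 (SD, n = 5), with intermediate means of 7.55, 7.83 and 7.84 in the stages between (log2 difference 3.47, SE 0.21, limma adjusted p = 2.0e-09 on 22 arrays and 4.2e-07 on 24). Its difference on 22 arrays was 2.06 without background correction and 2.02 with the authors' processed values. ILMN_1349776, detected on 0 of 5 early juvenile arrays and 4 of 5 late proestrus arrays, was higher on average in late proestrus (adjusted p = 0.0301, limma), where it lay at 7.75, 7.47 and 7.69 on replicates 1, 2 and 4 but at 5.24 and 5.74 on replicates 3 and 5, against 4.88 to 5.38 in early juvenile rats. The means differed by at least 2.11-fold after background correction, carried by those 3 arrays, but by a log2 difference of 0.63 without it and 0.61 with the authors' processed values. It lost the call without any 1 of 7 arrays, with an adjusted p of up to 0.0838. ILMN_1371267 fell by 2.06, from 10.86 ± 0.29 (SD, n = 5) to 8.80 ± 0.95 (SD, n = 5), and by 1.66 without background correction. ILMN_1358038, a bright probe at 14.36 ± 0.24 (SD, n = 5) in early juvenile rats, fell by 1.90 to 12.46 ± 0.68 (SD, n = 5), with a limma adjusted p of 0.0456 that rose above 0.05 without any 1 of 14 arrays. The planned fit called ILMN_1355623 alone, with 217 transcripts at an unadjusted p under 0.05. The 22-array fit called 754, of which 414 were higher and 340 lower in late proestrus. Neither stage holds one of the 2 arrays with low detection, and a fit of these 2 stages alone called 1279 transcripts, 655 higher and 624 lower. The 22-array count fell to 402 without early juvenile replicate 4.

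**Figure D4:**
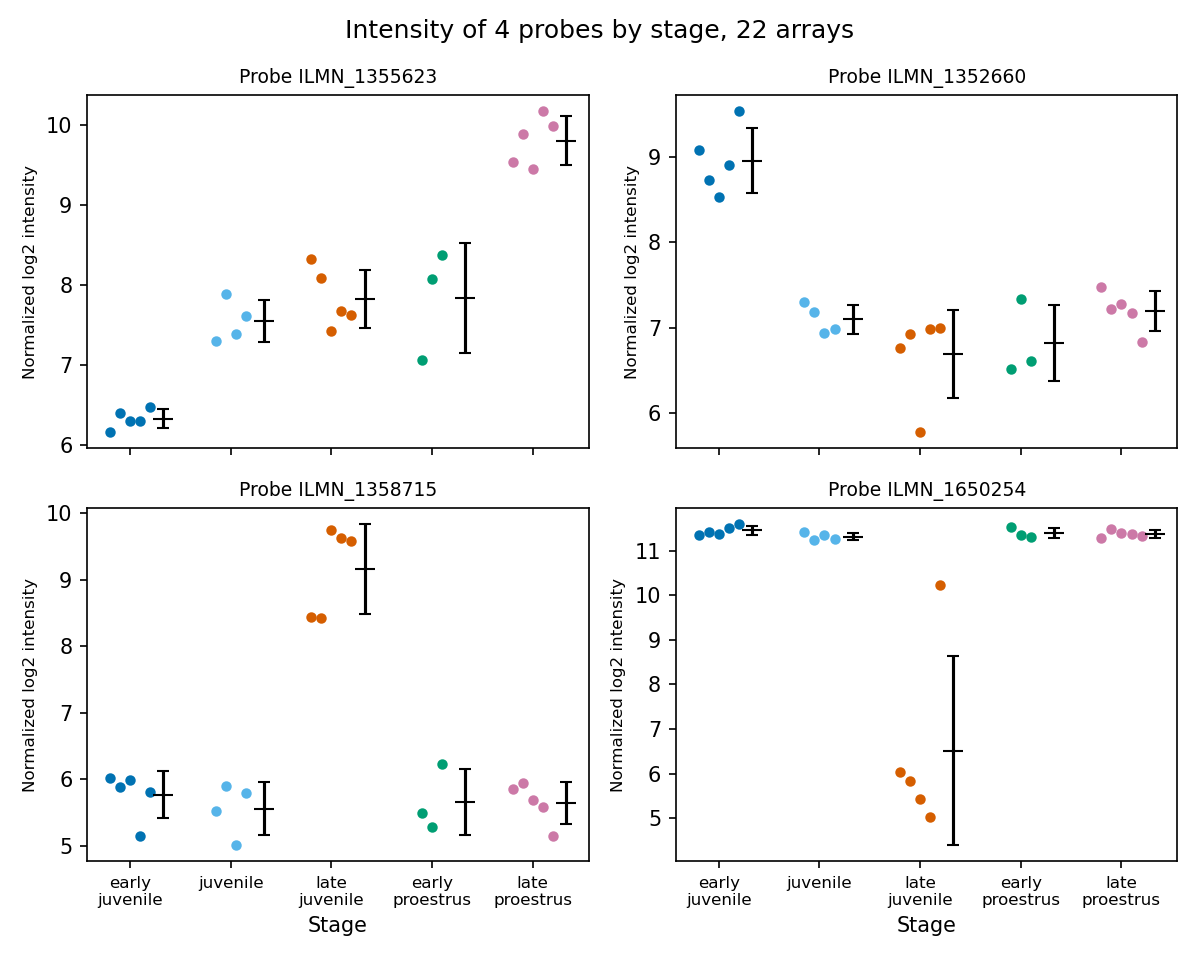
Normalized log2 intensity of 4 probes on each of 22 arrays by stage, with the mean ± SD of the stage in black. ILMN_1355623 rises from 6.33 to 9.80 over the 5 stages, ILMN_1352660 falls from 8.95 after the early juvenile stage, and ILMN_1358715 and ILMN_1650254 differ in the late juvenile stage, where 1 array of ILMN_1650254 lies at 10.2 and 4 lie between 5.02 and 6.04.

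The late juvenile stage was also compared with the first and the last stage, which was chosen after seeing the data. Late juvenile against early juvenile gave 30 transcripts on 24 arrays and 2736 on 22 (1349 higher, 1387 lower). Late proestrus against late juvenile gave 21 on 24 arrays and 2585 on 22 (1339 higher, 1246 lower).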

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

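The rank correlations in this part were chosen before their values were seen, and the test of the row order after the low signals had been seen. In each stage with 4 or 5 arrays, the highest and the lowest value were set against the others for detected share, mean signal and the probes named. Of 58 such groups of values, 14 held an array far from the rest of its stage, where chance flags about 5%.

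Juvenile replicate 4 detected 19.5% of probes against a mean of 48.3% on the other 4 juvenile arrays, and early proestrus replicate 2 detected 6.33% against 49.4%. If the rows of these arrays had only been placed against the wrong probes, as many probes would be bright as elsewhere. At most 71 probes exceeded a signal of 1000 on either array, against 1949 or more on each of the other 22, which argues against that. Over probes detected on all 22 arrays, juvenile replicate 4 kept the order of their mean with a rank correlation of 0.666, so little labelled RNA is a candidate cause there. Arrays of another tissue were not compared, so this value does not show that the sample is of the right kind. For early proestrus replicate 2 the rank correlation was -0.069, and a lost hybridisation, a blank and a foreign sample cannot be told apart, because hardly any signal stands above background. No biological explanation was tested for either array.

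The mean raw signal of early juvenile replicate 2 was 1000.2 against 844.6 ± 16.1 (SD) on the other 4 arrays, and that of late juvenile replicate 1 was 582.9 against 735.6 ± 18.8. Late proestrus replicate 3 detected 51.2% of probes against 49.2% on the other 4.

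Among the named probes, ILMN_1358038 was at 10.16 in juvenile replicate 5 and 10.25 in late juvenile replicate 1, the 2 dimmest of the 22 arrays, against means of 13.0 and 13.15 on the other arrays of their stages. ILMN_1650254 was at 10.24 in late juvenile replicate 5 against 5.58 ± 0.45 on the other 4. ILMN_1376698 was at 7.72 in late juvenile replicate 2 against 5.62 ± 0.16, and ILMN_1352660 at 5.78 in late juvenile replicate 3 against 6.92 ± 0.11. ILMN_1349776 was at 7.32 in juvenile replicate 1 against 5.15 ± 0.15 on 3 arrays. ILMN_1351340 was at 6.20 and ILMN_1358715 at 5.15 in early juvenile replicates 5 and 4, against 8.01 ± 0.11 and 5.92 ± 0.10. ILMN_1371267 was at 10.48 in late proestrus replicate 4 against 8.38 ± 0.18.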

How the results depend on the processing

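The fit without the 2 low-detection arrays, all settings on 22 arrays, the fit without their 2 dimmest arrays and brightness as a covariate were chosen after seeing the data, and the other settings before. Counts are given in the order any difference among the stages, juvenile against early juvenile, late juvenile against juvenile, early proestrus against late juvenile, late against early proestrus, and late proestrus against early juvenile, leaving out those within 1.5 times the count reported. On 24 arrays, 122 of 208 recomputed counts stayed within 1.5 times, and on 22 arrays 162 of 202 did. No named probe changed direction in 557 recomputed differences, and 153 of these no longer passed the threshold. The probes were picked for large differences on these same arrays, and most settings left out 1 array, so a change of direction was unlikely from the start. On 22 arrays all 17 named differences were smaller without background correction, at 35.5% to 98.4% of the log2 size, and with the authors' processed values, at 33.9% to 98%. What limits the planned fit is signal over background on the 2 low-detection arrays. Where no cause is named, the cause was not tested.

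On 24 arrays (19, 0, 27, 18, 1 and 1), no background correction gave 39, 2, 34 (10 higher, 24 lower, against 8 and 10) and 4 for all but late juvenile against juvenile and late against early proestrus, and the authors' processed values gave 40, 2, 32 (9 higher, 23 lower) and 4 for the same comparisons. In late proestrus against early juvenile both gave 2 higher and 2 lower. Median scaling gave 13, 5 (5 higher, 0 lower), 5 (0 higher, 5 lower), 0 and 7 (1 higher, 6 lower) from juvenile against early juvenile onward. No filter gave 41 for any difference and 1 for juvenile against early juvenile. The strict filter left 311 transcripts, since the 2 low-detection arrays must pass it, and gave 0 everywhere. Only the 2 stages in the fit gave 10 for late juvenile against juvenile, 0 for both early proestrus comparisons and 1279 for late proestrus against early juvenile. Array weights, which all but remove the 2 low-detection arrays, gave 4309, 942, 2851, 1967, 2 and 2144. The robust trend gave 1 for juvenile against early juvenile and 2 for late proestrus against early juvenile. Without both low-detection arrays the counts were 2676, 269, 1594, 741 and 754, late against early proestrus keeping 1.

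Leaving out each of the 24 arrays gave 10 to 344, 0 to 35, 11 to 431, 9 to 66, 0 to 1 and 1 to 43. The highest came without early proestrus replicate 2 in each but late against early proestrus. Without juvenile replicate 4 the counts were 66 for any difference, 45 for late juvenile against juvenile and 60 for early proestrus against late juvenile, and without early proestrus replicate 1 the last was 42. Late juvenile against juvenile moved beyond 1.5 times for 16 of the 24 arrays, down to 11 without late juvenile replicate 2 or 5. Late against early proestrus fell to 0 for 15.

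On 22 arrays (2676, 269, 1594, 741, 1 and 754), median scaling gave 4339, 153 (44 higher, 109 lower), 2615 (330 higher, 2285 lower), 1777 (1640 higher, 137 lower) and 490 (341 higher, 149 lower). Only the 2 stages in the fit gave 101, 585, 148, 0 and 1274 from juvenile against early juvenile onward. Array weights gave 4838, 949, 2893, 1967 and 2170. A fold of at least 1.5 gave 124, 713, 462 and 272. Without the 2 dimmest arrays the counts were 4163, 444, 2542, 1283 and 1471. Leaving out each array gave 2158 to 3476, 91 to 367, 1039 to 2410, 280 to 986, 1 to 1 and 402 to 1024. Juvenile against early juvenile fell to 91, 168, 115 and 152 without early juvenile replicates 1, 3, 4 and 5, and to 99, 158 and 127 without juvenile replicates 1, 2 and 3. Late juvenile against juvenile was 1039 without juvenile replicate 1 and 2410 without replicate 5. Early proestrus against late juvenile was 280 and 292 without early proestrus replicates 3 and 4. Late proestrus against early juvenile was 426, 486 and 402 without early juvenile replicates 1, 2 and 4, and 461 and 427 without late proestrus replicates 2 and 5.

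The slide as a block was not run, since the slide is not given in the sources used here, nor were the gene list alternatives. No paired analysis was possible because the replicate numbers in the labels differ between all arrays.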

Other observations

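With the late juvenile arrays left out, a fit chosen after seeing the data, most calls set early juvenile rats against the 3 later stages. Those 3 stages gave few calls among each other, but no simulation was run for this fit, so they may still differ. On these 17 arrays 495 of 11914 transcripts differed among the 4 stages. Against the early juvenile stage, 320 passed in the juvenile stage, 562 in early proestrus and 893 in late proestrus. Early proestrus against juvenile gave 0 with limma, with 505 (4.24%) at an unadjusted p under 0.05. Late proestrus against juvenile gave 2 with limma, with 780 (6.55%) at an unadjusted p under 0.05. The 2 were ILMN_1355623 (log2 difference 2.28, SE 0.22, limma adjusted p = 0.000113) and ILMN_1373253. The latter fell from 11.88 ± 0.12 (SD, n = 4) to 11.30 ± 0.05 (SD, n = 5) and was named after its value was seen. In the labels the early juvenile animals are numbered 164 to 168 and those of the 3 later stages 1 to 20. Stage, and animals or processing peculiar to the early juvenile group, therefore cannot be told apart in any comparison with that stage.

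In this part the counts over other splits, the brightness test, the tests that leave out an array and the covariate were chosen before their results were seen, though the covariate was not planned before the data were examined. The tests of transcripts with 2 levels within a stage, of stage against other properties of the late juvenile group and of the number of early proestrus arrays, and the simulation with 2 of them, were chosen after. Each comparison was recomputed on 100 splits of the same arrays, or on all 56 with 3 against 5, the real one included. On 24 arrays, 1 split of 100 gave as many calls as the real groups in any difference (19, highest other 1). The same held for late juvenile against juvenile (27, highest other 1) and early proestrus against late juvenile (18, highest other 4). It also held for late proestrus against early juvenile (1, highest other 0), so no other split tried reached these counts. The splits treat all arrays as exchangeable. A shift shared by the animals or processing of a stage would pass them as well as an effect of stage. In late against early proestrus 2 of 100 did (1, highest other 1). Though under 5%, that count of 1 transcript was also reached by another split and by 4 of 56 on 22 arrays, so chance stays open for it. With 0 calls, all 100 splits matched juvenile against early juvenile (highest other 0). On 22 arrays, 1 of 100 did so in any difference (2676, highest other 28), juvenile against early juvenile (269, highest other 9), late juvenile against juvenile (1594, highest other 1371) and late proestrus against early juvenile (754, highest other 10), and 2 of 56 in early proestrus against late juvenile (741, highest other 1341). In late against early proestrus 4 of 56 did (1, highest other 1), and chance is not excluded there. The split with 1371 calls sets the other 4 late juvenile arrays against the juvenile arrays and late juvenile replicate 1. The one with 1341 exchanges that array with early proestrus replicate 1, which points to a structure of the arrays that the stages do not fully follow.

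The late juvenile arrays stood apart from both earlier and later stages. They were also dimmer. An axis was drawn from the mean of the early juvenile, juvenile and late proestrus stages, without early proestrus, to late juvenile. Along it the within-stage slope on brightness in the other arrays predicts a shift of at most 0.178 (upper 95% limit). The late juvenile arrays, however, averaged 0.818 when each was left out of its own axis. Late juvenile against juvenile gave 1602 with brightness as a covariate, against 1594. It gave 1227 or more without any single late juvenile array, which argues against 1 array as the source. Stage, and animals or processing peculiar to this group, cannot be told apart over its 5 arrays. In the labels its animals are numbered 28 to 37, outside the 1 to 20 of the juvenile, early proestrus and late proestrus animals. Comparisons among those stages gave 0, 1 and 2 calls on the 17 arrays without the late juvenile stage. The comparisons with the early or late juvenile stage gave between 269 and 2736 on 22 arrays, so calls followed the number blocks as well as the stages. Slide and scan date are not given in the sources used here.

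A hypothesis is that the late juvenile rats carried gene variants that were rarer in the other rats, as rats of another litter or colony may. It arose from ILMN_1650254, near 11.4 on 17 arrays and divided within the late juvenile stage. Variants confined to these rats do not account for 2 other named probes, whose late juvenile level also occurs elsewhere: ILMN_1374870, at 10.06 to 10.23 in late juvenile rats, was at 10.09 and 10.24 in early juvenile replicates 2 and 3, and ILMN_1349776, at 7.13 to 8.23, was at 7.32 in juvenile replicate 1 and at 7.75, 7.47 and 7.69 in late proestrus replicates 1, 2 and 4. A variant under a probe or in a gene's control region can give 2 separate levels within a stage. Unlinked variants divide the rats in different ways, whereas 1 common shift gives no such division beyond scatter between arrays. In 5 unchanged simulated arrays, independent scatter alone gave 2 levels for 16 of 8556 transcripts. By that rule the 5 stages, in order of age, held 14, 137, 74, 42 and 28. No baseline was simulated for 4 arrays, or with little spread asked for elsewhere. The first test, which also asked for little spread elsewhere, went against the hypothesis. It found 35 such transcripts within the late juvenile stage, but 71 within the juvenile stage. The 35 fell into 9 divisions of the 5 arrays, and 20 set late juvenile replicate 1 alone apart, so a common shift or a subset of arrays stays open. Of the 35, 1 divided the arrays as the animal numbers do. This was ILMN_1372101, at 13.74 and 13.37 in animals 28 and 29 and at 9.94 to 10.39 in animals 35 to 37. The named probe ILMN_1358715, at 8.43 and 8.42 against 9.58 to 9.74, divided them the same way. ILMN_1650254 and ILMN_1376698 each set a single other array apart. A second version, made after that result, left out the 2 dimmest arrays, juvenile replicate 5 and late juvenile replicate 1. It found 27 such transcripts in the 4 late juvenile arrays, at most 10 in any 4 early juvenile or late proestrus arrays, and 6 of 7 possible divisions. No more than 7 transcripts shared 1 division. Those 7 set replicate 2, animal 29, apart from the other late juvenile arrays, animals 35 to 37, as the animal numbers do. The juvenile stage, left with 3 arrays, is absent from that comparison, and with late juvenile replicate 1 alone left out the late juvenile count was 26, against 71 in the 4 juvenile arrays, which include replicate 5, the dimmest of the 22. The spread of divisions argues against 2 batches as the source of all 27 transcripts, while batches with scatter between arrays could account for some. Segregating variants and a common shift with scatter between arrays stay open, because the transcripts were picked for their 2 levels and the excess over other stages rests on which arrays were left out.

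Early proestrus replicate 1, labelled 29 days like the late juvenile rats, lay at 0.427 along the late juvenile axis, while the other 2 arrays of its stage lay at 0.00761 and 0.0164. Juvenile replicate 5, of 26 days and the dimmest of the 22 arrays, lay at 0.351.

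Only ILMN_1355623 passed between early and late proestrus. In simulated data, 87% of 2-fold changes in this comparison were recovered with 3 arrays against 5, and 38.8% of 1.41-fold changes. With independent noise, 3 arrays are thus not too few to find most 2-fold changes, while smaller ones could have been missed. The simulation cannot show what shifts of whole real arrays would hide. Without early proestrus replicate 1 the count stayed at 1, and early proestrus against late juvenile gave 957 with the 2 arrays left. With 2 simulated arrays against 5, 80.9% of 2-fold changes and 31.3% of 1.41-fold changes were recovered. If noise were independent, many 2-fold changes hidden by the position of early proestrus replicate 1 would thus have appeared without it. Smaller changes, and larger ones under noise shared across an array, stay open. That few transcripts differ by 2-fold or more between these stages stays open as a biological explanation and was not tested on other animals.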
